A study of Mus musculus with 37 samples.

How the data were processed

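The study profiled RNA bound to tagged ribosomes in mouse lymph nodes and spleen. In RiboTag mice a Cre recombinase switches on a copy of the ribosomal protein Rpl22 that carries a haemagglutinin tag, and an antibody against the tag then pulls down ribosomes with the mRNA on them. Here the Cre was expressed from the CD169 (Siglec1) locus, which is active in the macrophages that line lymph node sinuses. Per the labels, the mice were homozygous for both alleles, RNA was purified with a PicoPure kit, and libraries were made from polyadenylated RNA.

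The deposited table holds estimated counts for 56351 genes in 37 libraries, not scaled between libraries. Per the submitters' processing notes, kallisto, edgeR and limma were used, with no version or role given for any of them. The notes name the genome builds GRCm39 and mm10 together, so the build behind the deposited counts is ambiguous and no coordinates are given here. The step from transcripts to genes is not stated. Of all deposited count values 32.8% were not whole numbers with no tolerance, 99.3% of the non-zero values lay further than 0.001 from a whole number, and all were rounded before testing. A scaling step before deposit is neither stated nor excluded, so what is called a count here need not be a number of reads. kallisto shares reads between near-identical transcripts, so counts of paralogs and pseudogenes, such as Hba-a1 and Hba-a2, Rpl19-ps1 or Rpl10l, are uncertain. The labels do not say whether the counting used strand, so overlapping and antisense genes are uncertain too. Gene symbols are those of the deposited table. Of its gene identifiers, 51498 matched a GENCODE M21 name and 4853 did not, and 91.7% of the matched ones had the same symbol. The 211 genes with no symbol held between 0.0159% and 0.115% of a library's counts.

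The 37 libraries were 11 lymph node sites and spleen with 3 libraries each, and 1 isotype control from jejunal node. No library was left out of the planned tests except the isotype control, which entered no model. Library totals ranged from 221911 to 69139450 counts, a 312-fold range. In the shallowest library 3 counts correspond to 13.5 CPM (counts scaled to a library total of 1000000) and in the deepest to 0.0434 CPM. These floors, the isotype comparison and the sex-linked genes use plain library totals. Every other CPM is scaled by the TMM-adjusted totals of its model, so the same libraries have other CPM in the model of 36 libraries than in that of 22. These floors cover counting error only, since PCR copies are not independent molecules. The 36 pairs of replicates were all different libraries, with a chi-square per degree of freedom between 13.2 and 221, so the spread between replicates was far above counting error.

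Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 16294 genes. Libraries were scaled with TMM, and a quasi-likelihood model with robust settings and 1 mean per group was fitted to all 36 libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Errors of log2 fold changes are standard errors recovered from the fold change and its F statistic, and errors of CPM are SD over libraries. The first contrast was the mean of duodenal, jejunal and ileal nodes against the mean of 5 nodes called non-digestive here (inguinal, super cervical, deep cervical, mediastinal, iliac). That name rests on titles that list no digestive organ for them, and what these nodes drain was not measured. The same 3 small-intestinal nodes were set against the ceco-colonic node, and duodenal against ileal. Liver and celiac were set against the same 5 nodes, and the 11 nodes against spleen. An F test of 10 contrasts asked for any difference among the 11 nodes. A fold against a group with no counts is given as a lower bound, computed against 3 counts over that group.

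Before the data were examined, 42 gene lists were fixed: 15 of cell programs, 16 of cell types, 10 of neighbouring organs and 1 of sex-linked genes. Lists with 3 or more measured genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. Adjusted p-values for lists run over the lists within a contrast. The rule for naming genes was fixed at the same time. In each contrast it takes Siglec1, Rpl22, Cd68, Adgre1, Csf1r and Marco, then up to 8 genes with the largest fold change in each direction, and up to 4 genes of a described list. The large changes had to pass the threshold, reach 10 CPM on the higher side and keep their sign in each replicate number. Predicted genes, immunoglobulin segments and genes of neighbouring organs were excluded from them. For the F test the rule takes the 8 genes with the smallest p. Genes plotted or listed by node were chosen after their values were seen. Some genes that the rule takes are not reported here.

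A further set of contrasts was added after the library totals and the planned results had been seen. It uses only the 22 libraries of 1000000 counts or more, which removes every duodenal, liver, celiac and iliac library and leaves 1 jejunal library. In that model 19702 genes were tested: ileal against the mean of inguinal, super cervical, deep cervical and mediastinal nodes; ileal against ceco-colonic; 7 nodes against spleen; and an F test among the 7 nodes. The naming rule was applied to them unchanged.

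The alternatives fixed before the data were examined were size factors in place of TMM, no filter or a stricter filter (5 CPM in 3 libraries), limma voom, DESeq2 1.42.0, a replicate block, genes at 2 times the isotype control or more, other reference nodes, node means as replicates and leaving out each library in turn. Alternatives added after seeing the data were the restriction to libraries of 1000000 counts or more, thinning those libraries to 1000000, and removal of 3 abundant features. The comparison with the isotype control uses log2 ratios of CPM with a pseudocount of 1, and list medians are set against 10000 random lists matched on mean expression.

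The models were tested on simulated counts drawn from 1 overall mean per gene and the real library sizes, with known changes in a set of genes. The simulation held no other difference between nodes and no shift of all genes, so its shares need not hold for the data. False calls made up 3.33% (liver and celiac against non-digestive nodes) to 11.3% of the simulated calls, and 8.49% for small-intestinal against non-digestive nodes. For small-intestinal against non-digestive nodes, over 16294 genes, 8.75% of 2-fold, 63.3% of 4-fold and 86.7% of 8-fold changes were recovered. For duodenal against ileal node, over 16294 genes, the shares were 0% of 2-fold, 6.67% of 4-fold and 30% of 8-fold changes. For ileal against the 4 other nodes in libraries of 1000000 counts or more, over 19702 genes, they were 6.25%, 71.7% and 90%, and 11.3% of the calls in that simulation were false. Other splits of the libraries were drawn with a fixed seed, up to 60 per contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.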

Results

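RNA from immunoprecipitated ribosomes of CD169-Cre RiboTag mice was sequenced from 11 lymph node sites (duodenal, jejunal, ileal, ceco-colonic, liver, celiac, inguinal, super cervical, deep cervical, mediastinal and iliac) and from spleen, with 3 libraries per site and 1 isotype control library from jejunal node. Total counts ran from 221911 in a duodenal library to 69139450 in a mediastinal library. The ileal libraries held 18811172 to 31849079 counts and the mediastinal ones 41240156 to 69139450, whereas every duodenal, liver, celiac and iliac library held under 1000000. Gm19220, Rn18s-rs5 and Lars2, features that carry ribosomal sequence, took 39% to 85.6% of the counts in the 14 libraries under 1000000 and 1.97% to 42.7% in the other 22. Genes with 10 or more counts numbered 692 in the poorest library and 22256 in the richest.

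**Figure D1:**
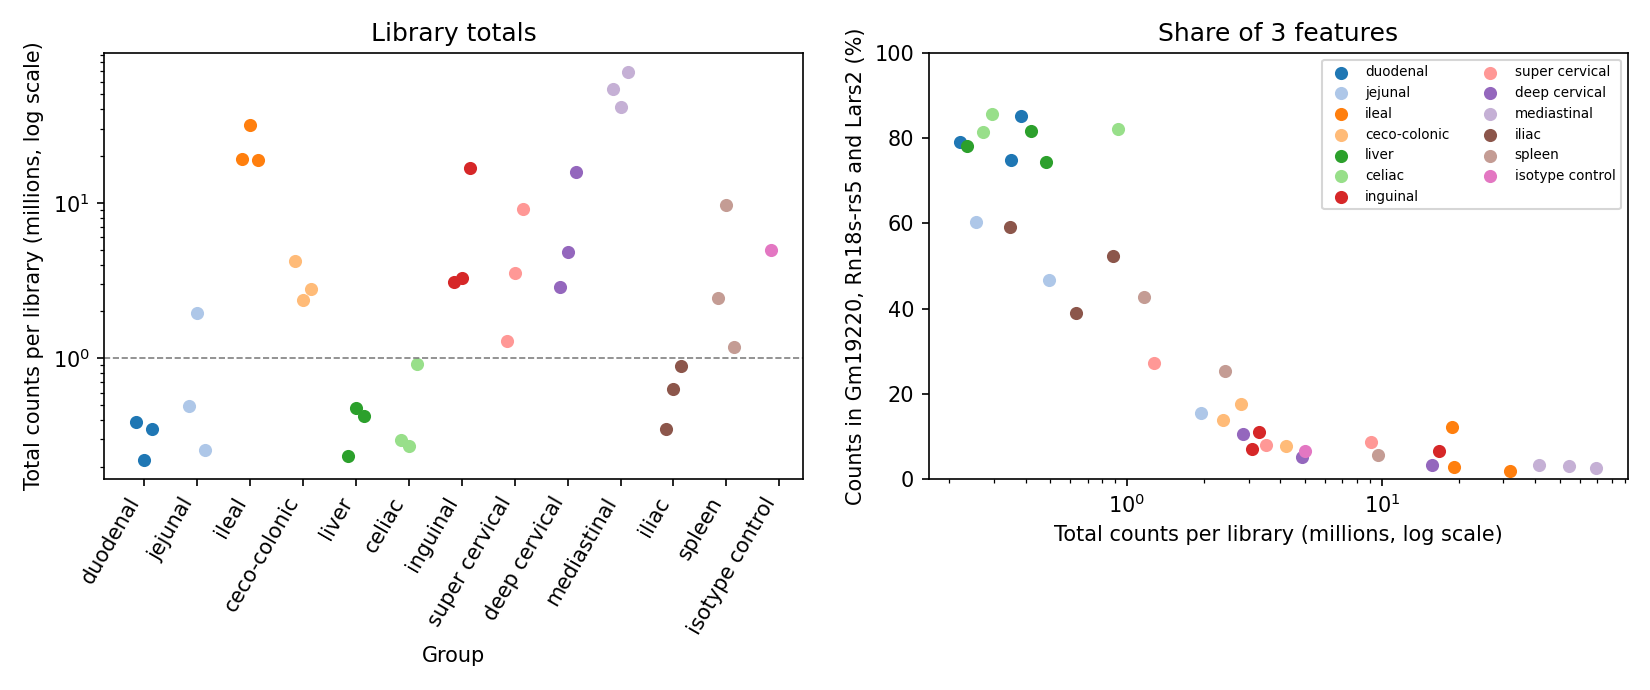
Total counts per library by group (left, log scale, 1 point per library, dashed line at 1000000), and the percentage of counts in Gm19220, Rn18s-rs5 and Lars2 against total counts (right, log x axis). Libraries under 1000000 counts all lie at 39% or above, and the 3 mediastinal libraries at 3.16% or below.

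The isotype control addresses how specific the pull-down was. Its library held 5002926 counts, more than the 495246, 1950752 and 256282 of the 3 jejunal pull-downs. Genes with 10 or more counts numbered 9370 against 2548, 7267 and 1294. In the isotype library 3 counts correspond to 0.6 CPM and in the jejunal libraries to 1.54 to 11.7 CPM. Ratios of genes with few counts thus depend on depth as well. Marco, a scavenger receptor of sinus macrophages, averaged 2390 ± 2080 CPM (SD, n = 3) in jejunal node against 17 CPM in the isotype library, a log2 ratio of 7.05. C1qa, a subunit of the first complement component, averaged 264 ± 214 CPM against 4.4, a log2 ratio of 5.62. The nuclear noncoding RNA Malat1 went the other way, with 65100 ± 44700 CPM in jejunal node and 266000 in the isotype library. Median log2 ratios over fixed lists were 2.55 for complement, 2.21 for lymphatic endothelium, 1.82 for lysosome and 1.09 for sinus and resident macrophage genes, at percentiles 100, 100, 100 and 98.2 of random lists. Lists of other cells were high too, among them adipocyte genes at 2.06, erythroid at 1.97, lung epithelium at 1.55 and blood endothelium at 1.01 (percentiles 100, 99.9, 96.9 and 99.5). B cell genes had a median of -0.69 and T cell genes of -0.44, at percentiles 8.24 and 4.66. Without jejunal replicate 2 the medians were 1.45 for lymphatic endothelium, 0.97 for adipocyte, -1.39 for B cell and -0.74 for T cell genes, and without replicate 3 they were 0.97 for lung epithelium and -0.19 for T cell genes. With TMM scaling lung epithelium changed sign to -0.57, and erythroid, B cell and T cell genes stood at 3.02, -1.17 and -1.04. Csf1r, the receptor for the macrophage growth factor CSF1, was level at 7.14 ± 7.75 against 8.19 CPM. Siglec1, whose locus carries the Cre, had 0 counts in all 4 of these libraries. With a single isotype library this comparison has no replicate check, and the third jejunal library stood apart, with 97.5 CPM of Marco against 2910 and 4150 in the others. Medians for jejunal libraries taken singly ran from -0.12 to 3.49 for complement and -0.84 to 2.99 for lymphatic endothelium genes. They ran from -0.09 to 1.94 for lysosome and 0 to 1.53 for sinus and resident macrophage genes, so not every library showed a rise.

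The series title asks what sets small-intestinal nodes apart. Over all libraries, duodenal, jejunal and ileal nodes together had more Nkx2-3, a homeobox factor of gut and splenic stroma (log2 fold change 4.64 ± 1.75, adjusted p = 0.0473), and more Lepr, the leptin receptor (3.62 ± 0.94, adjusted p = 0.00834), than the 5 nodes called non-digestive here. The immunoglobulin constant genes Igha and Ighg1 were also higher, by 2.03 ± 0.66 and 1.76 ± 0.60 (adjusted p = 0.0247 and 0.0251). The monocyte chemokine Ccl8 was lower (-7.37 ± 1.02, adjusted p = 1.72e-05), as were the B cell chemokine Cxcl13 (-4.78 ± 1.16, adjusted p = 0.00446) and the epithelial keratin Krt19 (-7.45 ± 1.79, adjusted p = 0.00476). Among chemokine genes 4 of 17 were lower and 0 higher, the same when adjusted over the list alone (camera adjusted p = 0.0412; adjusted p = 0.304 with an estimated correlation). For the ileal node in the deeper libraries the chemokine list did not pass (camera adjusted p = 0.362; adjusted p = 0.698 with an estimated correlation). Pancreatic acinar genes, a marker list for neighbouring tissue, had 3 of 4 measured members higher, also adjusted over the list alone (camera adjusted p = 0.00907; adjusted p = 0.304 with an estimated correlation).

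In total 4398 of 16294 genes passed the threshold, 861 higher and 3537 lower in the small-intestinal nodes. The median log2 fold change of all genes was -0.91, so directions stand relative to that shift. The count depended on the reference: against all 8 other nodes 14 genes passed, 8 higher and 6 lower. It was 3022 against the inguinal node alone (73 higher, 2949 lower) and 4343 against inguinal and super cervical nodes (172 higher, 4171 lower). With node means as replicates 0 genes passed in limma, where 747 had an unadjusted p under 0.05. Nkx2-3 lost its call when duodenal replicate 3 was left out (2.30, adjusted p = 1), and Igha when jejunal replicate 2 was left out (1.12, adjusted p = 0.166).

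Among libraries of 1000000 counts or more, the only small-intestinal site with replicates was the ileal node, and it was set against inguinal, super cervical, deep cervical and mediastinal nodes. The homeobox genes Nkx2-3, Hoxc8 and Hoxb7 were higher in the ileal node, Nkx2-3 by 6.58 ± 0.74, Hoxc8 by 5.22 ± 0.30 and Hoxb7 by 4.83 ± 0.42 on the log2 scale (adjusted p = 2.75e-05, 1.3e-12 and 1.52e-08). Nkx2-3 averaged 23.8 ± 1.57 CPM in ileal and 29.3 ± 2.72 in ceco-colonic node, against 0.0171 in inguinal and 0.0438 in mediastinal node (n = 3 each). A single super cervical library held 31.5 CPM and the other two 0, and DESeq2 gave no adjusted p for this gene. Hoxc8 followed a different division, with 64.6 ± 19.3 CPM in ileal, 92.9 ± 23.7 in ceco-colonic and 64.1 ± 19.5 in inguinal node, and 0.452 ± 0.456 in deep cervical node.

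Some macrophage genes were higher in the ileal node. Adgre1, which encodes F4/80, rose by 3.15 ± 0.47 (10.6 ± 3.84 against 1.99 ± 2.31 CPM, adjusted p = 8.25e-05), Marco by 2.28 ± 0.44 (6273 ± 639 against 1408 ± 700 CPM, adjusted p = 0.00235) and the macrophage-secreted protein Cd5l by 2.92 ± 0.34 (adjusted p = 1.43e-06). Of 18 sinus and resident macrophage genes 4 were higher and 0 lower; adjusted over the list alone, 7 were higher and 1 lower (camera adjusted p = 0.000143; adjusted p = 0.251 with an estimated correlation). The complement genes C1qa and C1qc rose by 1.57 ± 0.34 and 1.62 ± 0.32, the list's 2 calls among 12 genes, or 3 adjusted over the list alone (camera adjusted p = 0.00074; adjusted p = 0.113 with an estimated correlation). Csf1r, Cd68, Rpl22 and Siglec1 did not pass (adjusted p = 0.296, 0.96, 1 and 1). Siglec1 stayed near the floor, at 0.429 ± 0.196 CPM in the ileal node. The single jejunal library of this depth held 15.1 CPM of Adgre1 and 6816 CPM of Marco. A rise limited to the ileal node is thus not shown for these genes.

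Lymphatic endothelium genes rose in the ileal node as a group. Of 13 measured, 9 were higher and 0 lower, or 10 and 0 adjusted over the list alone, and the list passed with an estimated correlation as well (camera adjusted p = 2.12e-10; adjusted p = 0.000616 with an estimated correlation). Lyve1, a hyaluronan receptor, rose by 2.43 ± 0.37 (59.5 ± 7.59 against 14 ± 11.3 CPM) and Cldn5, a tight junction protein of endothelium, by 2.32 ± 0.35 (adjusted p = 8.83e-05 and 8.25e-05). Marco and Madcam1, the gut homing addressin (1.53 ± 0.33, adjusted p = 0.00515), are members of this list. Without ileal replicate 3, 4 members passed. Dendritic cell genes had 4 of 15 members higher, among them Clec9a by 2.56 ± 0.36 and Batf3 by 1.57 ± 0.28, and 5 adjusted over the list alone (camera adjusted p = 4.64e-05; adjusted p = 0.0208 with an estimated correlation). Plasma cell genes had 4 of 16 higher, the same adjusted over the list alone. Among them were Ighg1 by 5.16 ± 0.36 (493 ± 204 against 21.6 ± 21.4 CPM) and Igha by 4.54 ± 0.76 (1690 ± 288 against 161 ± 290 CPM), with adjusted p = 7.58e-11 and 0.00256 (camera adjusted p = 1.09e-05; adjusted p = 0.0965 with an estimated correlation).

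**Figure D2:**
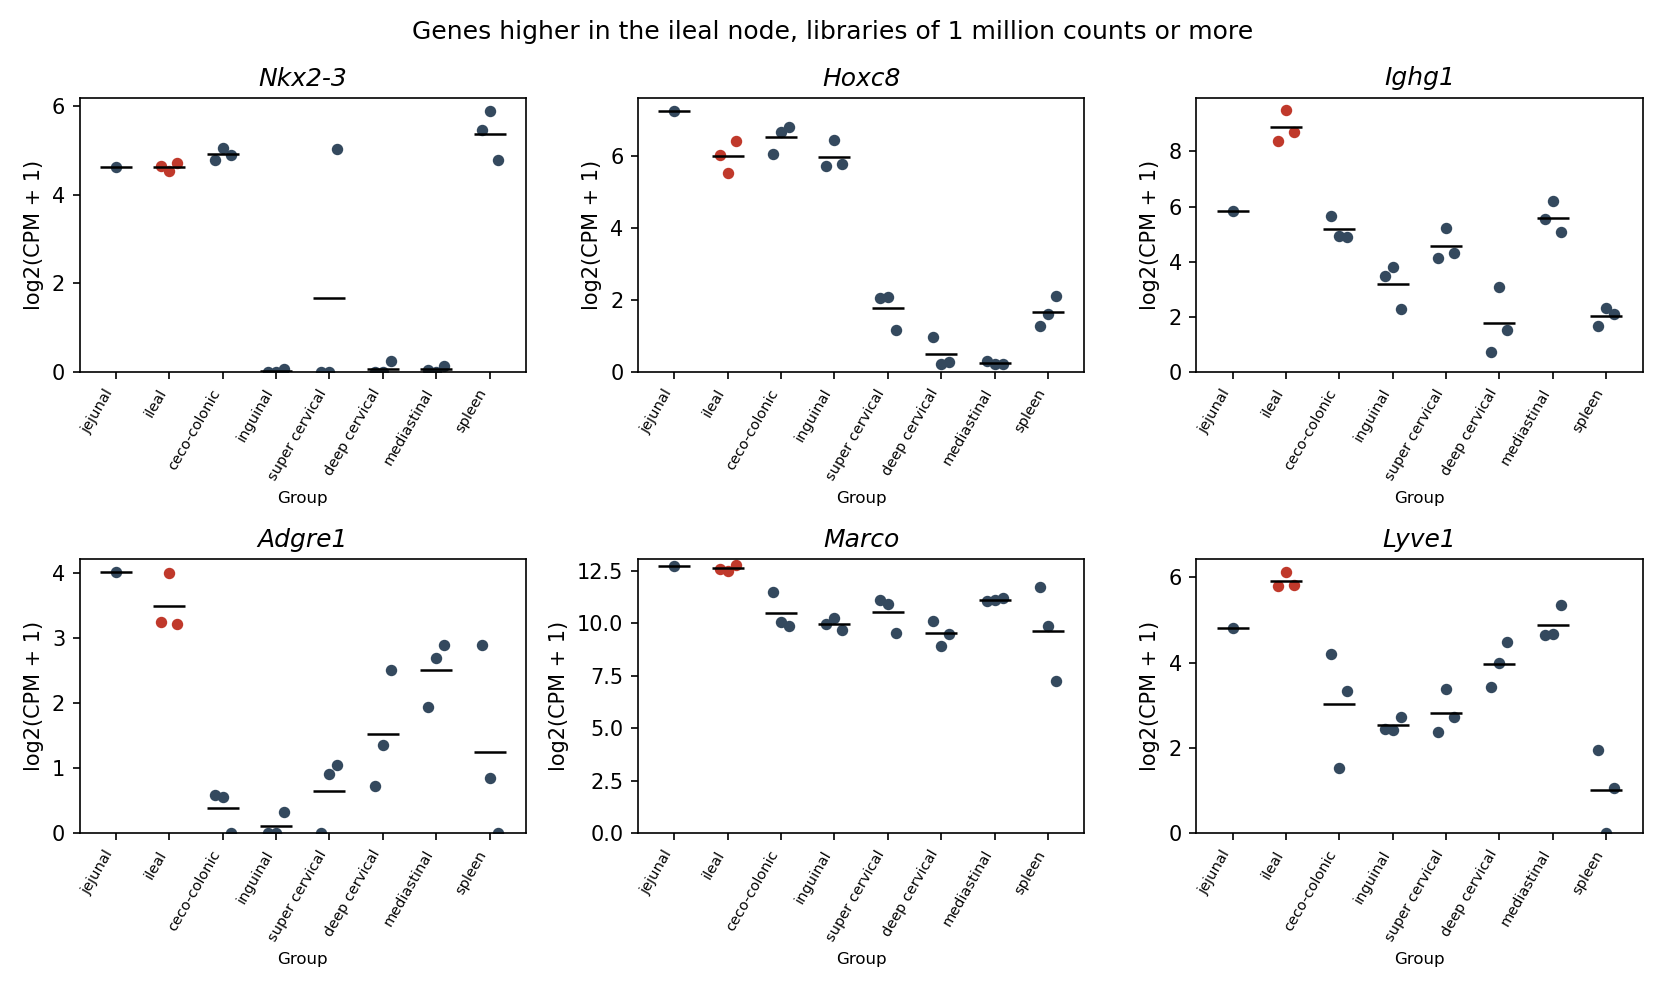
log2(CPM + 1) of Nkx2-3, Hoxc8, Ighg1, Adgre1, Marco and Lyve1 in libraries of 1000000 counts or more, 1 point per library, with ileal libraries in red and horizontal bars at group means. Nkx2-3 averaged 23.8 CPM in ileal and 29.3 CPM in ceco-colonic node, and Hoxc8 64.1 CPM in inguinal node.

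Genes lower in the ileal node included mast cell proteases and epithelial genes. Mcpt4, a mast cell chymase, was lower by a log2 fold change of -6.16 ± 0.67 and Cma1 of -4.48 ± 0.57 (adjusted p = 8.46e-07 and 8.56e-06). Both were also lower in the ceco-colonic node against the 4 non-digestive nodes (-10.4 and -5.07, adjusted p = 0.000332 and 0.00263). In the ileal node Ccl8 was lower too (-5.16 ± 0.48, adjusted p = 2.6e-08). Salivary gland genes had 5 of 12 members lower, 9 adjusted over the list alone (camera adjusted p = 3.22e-12; adjusted p = 0.00378 with an estimated correlation). Lung epithelium genes had 3 of 10 lower, 5 adjusted over the list alone (camera adjusted p = 9.21e-11; adjusted p = 0.00194 with an estimated correlation). These transcripts sat in particular reference nodes: the salivary protein Smr3a averaged 1820 ± 1770 CPM in super cervical node and the airway secretoglobin Scgb1a1 905 ± 782 CPM in mediastinal node. Overall 570 of 19702 genes passed, 318 higher and 252 lower. The count was 261, 236 and 256 without ileal replicate 1, 2 and 3, and DESeq2 and limma voom called 369 and 468 genes higher with 508 and 534 lower. Setting inguinal, super cervical, deep cervical or mediastinal node in turn against the rest of these 5 nodes gave 5420, 2249, 6131 and 7516 genes, all above the ileal count.

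The contrast with the ceco-colonic node separates small from large intestinal drainage. Over all 36 libraries, some lymphocyte genes were lower in the small-intestinal nodes. Cd79a, part of the B cell receptor, changed by -3.02 ± 0.59 (adjusted p = 0.00111) and the T cell adhesion molecule Cd2 by -5.79 ± 1.02 (adjusted p = 0.000885). B cell genes had 9 of 14 lower and T cell genes 6 of 16, or 10 and 9 adjusted over the list alone (camera adjusted p = 0.0418 for both; adjusted p = 0.742 and 0.705 with an estimated correlation). In all, 3259 of 16294 genes passed, 116 higher and 3143 lower, with a median log2 fold change of -1.004 over all genes. In libraries of 1000000 counts or more, where 3 ileal libraries and 1 jejunal library stood for the small intestine, 17 genes passed, 15 higher and 2 lower. B cell and T cell genes did not pass as lists for the ileal node alone in those libraries (camera adjusted p = 0.492 and 0.129; adjusted p = 0.824 and 0.573 with an estimated correlation).

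In those deeper libraries the ileal node itself exceeded the ceco-colonic node in some macrophage genes and in the lymphatic endothelium gene Lyve1. Mrc1, the mannose receptor, was higher by 3.35 ± 0.55 (52.3 ± 11.2 against 4.89 ± 3.43 CPM, adjusted p = 0.00273), Adgre1 by 4.88 ± 0.95 (adjusted p = 0.0169) and Cd5l by 2.84 ± 0.53 (adjusted p = 0.0113). Mrc1 was also lower in the ceco-colonic node than in the 4 non-digestive nodes (-1.97 ± 0.475, adjusted p = 0.0212), so part of its fold lies there. Adgre1 stood at 0 to 0.505 CPM in ceco-colonic libraries, where 3 counts correspond to 0.715 to 1.26 CPM, so the size of its fold is uncertain. Ighg1 and the myeloid hexokinase Hk3 were higher by 3.76 ± 0.58 and 3.95 ± 0.54 (adjusted p = 0.0018 and 0.000467), and the T-box factor Eomes was lower (-2.40 ± 0.47, adjusted p = 0.0181). Of 18 sinus and resident macrophage genes 4 were higher, or 11 with 1 lower adjusted over the list alone (camera adjusted p = 5.56e-05; adjusted p = 0.573 with an estimated correlation). Of 13 lymphatic endothelium genes 1 was higher, Lyve1 by 2.60 ± 0.57 (adjusted p = 0.0382), or 4 adjusted over the list alone (camera adjusted p = 0.000661; adjusted p = 0.066 with an estimated correlation). Marco did not pass (adjusted p = 0.175). Altogether 52 of 19702 genes passed, 42 higher and 10 lower, and 3 passed without ceco-colonic replicate 3 and 8 without replicate 2. DESeq2 called 612 genes and limma voom 92.

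The duodenal and ileal nodes mark opposite ends of the small intestine. Marco fell by 6.31 ± 1.12 on the log2 scale in the duodenal node, with 65.7 ± 73.9 against 5139 ± 539 CPM when scaled over all 36 libraries (adjusted p = 3.67e-05), and Csf1r by 4.21 ± 1.11 (adjusted p = 0.00202). Several abundant genes had 0 duodenal counts: Atp5f1e, a subunit of ATP synthase, was at least 137-fold lower, and the selenoprotein Selenow at least 54-fold. MHC class II presentation genes had 11 of 14 lower, lysosome genes 15 of 21 and B cell genes 11 of 14, or 12, 17 and 11 adjusted over the list alone (camera adjusted p = 0.0336, 0.0336 and 0.041; adjusted p = 0.497, 0.528 and 0.539 with an estimated correlation). Among genes higher in the duodenal node was parathyroid hormone, Pth (7.44 ± 1.52, adjusted p = 0.000312), on 30 counts against 17; the deep cervical libraries held 120217 Pth counts and 27 of the 33 other libraries at least 1. A total of 7445 of 16294 genes passed, 1798 higher and 5647 lower. The duodenal libraries held 221911 to 385071 counts, 74.8% to 85.1% of them in the 3 ribosomal features, and the median log2 fold change of all genes was -2.35.

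Liver and celiac nodes, the other upper-abdominal sites, were set against the 5 non-digestive nodes. Marco fell by 3.36 ± 0.65 (91.1 ± 39.2 against 1050 ± 633 CPM, adjusted p = 3.53e-05) and Csf1r by 1.59 ± 0.60 (adjusted p = 0.0245), less than the median gene. Sinus and resident macrophage genes had 11 of 17 lower and 1 higher, the same adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.368; adjusted p = 0.753 with an estimated correlation). Ccl8 had 0 counts in the 6 libraries and was at least 40.8-fold lower. The interleukin-12 receptor gene Il12rb2 was higher (9.44 ± 1.25, adjusted p = 2.21e-07) on 22 counts. B cell genes had 13 of 14 members lower, the same adjusted over the list alone (camera adjusted p = 0.0605; adjusted p = 0.733 with an estimated correlation). None of the 41 lists passed in camera with either correlation, though 9 and 2 had an unadjusted p under 0.05. A total of 7709 of 16294 genes passed, 1819 higher and 5890 lower. All 6 libraries held under 1000000 counts, and the median log2 fold change of all genes was -2.15.

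Red cell genes were lower in nodes than in spleen. The alpha-globin gene Hba-a2 was lower in nodes by a log2 fold change of -7.09 ± 0.37 (443 ± 844 against 23520 ± 23600 CPM scaled over all 36 libraries, adjusted p = 2.99e-22), and Alas2, which starts haem synthesis in red cell precursors, of -7.91 ± 0.58 (adjusted p = 8.3e-15). All 7 measured erythroid genes were lower in nodes, also adjusted over the list alone (camera adjusted p = 4.05e-15; adjusted p = 0.000823 with an estimated correlation). The neutrophil genes S100a9 and Camp were lower by -7.52 ± 0.72 and -7.98 ± 0.58, 2 of the 4 calls among 8 neutrophil genes, or 5 adjusted over the list alone (camera adjusted p = 0.00413; adjusted p = 0.0499 with an estimated correlation). Proliferation genes had 11 of 18 lower, the same adjusted over the list alone, among them Top2a by -3.87 ± 0.38 (camera adjusted p = 0.000572; adjusted p = 0.32 with an estimated correlation). The interferon-induced gene Ifit1 was lower in nodes by -2.02 ± 0.38 (adjusted p = 2.61e-05), a call that size factors in place of TMM ended (-0.84, adjusted p = 0.143).

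Nodes exceeded spleen in the MHC class II gene H2-Ab1 (2.73 ± 0.69, adjusted p = 0.00159) and in Fabp4, a fatty acid binding protein of fat cells, endothelium and macrophages (1313 ± 1640 against 35.5 ± 25.1 CPM, adjusted p = 0.000195). Adipocyte genes, a list for neighbouring fat, had 7 of 13 higher in nodes, 8 adjusted over the list alone (camera adjusted p = 7.73e-05; adjusted p = 0.312 with an estimated correlation). The extracellular matrix protein vitronectin, Vtn, was higher by 6.87 ± 1.05 (adjusted p = 6.46e-07). Of 16294 genes 4711 passed, 479 higher and 4232 lower in nodes with TMM scaling. That balance turned with the scaling: size factors gave 1667 higher and 941 lower, DESeq2 5883 and 1202, and limma voom 3118 and 3229, with medians over all genes of -0.77, 0.52, 0.93 and 0.06 in the same order. In libraries of 1000000 counts or more 9815 of 19702 genes passed, 5202 higher and 4613 lower, and Hba-a2, H2-Ab1 and Fabp4 changed by -6.17 ± 0.40, 4.24 ± 0.56 and 5.75 ± 0.58. Proliferation and neutrophil genes did not pass as lists there (camera adjusted p = 0.0988 and 0.0538; adjusted p = 0.717 and 0.415 with an estimated correlation), and erythroid genes passed with the preset correlation alone (camera adjusted p = 8.66e-08; adjusted p = 0.415 with an estimated correlation).

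Among the 11 nodes the genes with the smallest p were Foxe1, a thyroid transcription factor, Scg2, a secretogranin of endocrine and nerve cells, Tcap, the titin cap protein of striated muscle, and Iyd, a thyroid deiodinase (adjusted p = 2.21e-22, 5.94e-21, 1.17e-19 and 1.72e-18). Foxe1 averaged 407 ± 91 CPM in deep cervical node and 0.131 ± 0.11 in mediastinal node among libraries of 1000000 counts or more. The F test among the 11 nodes called 13835 of 16294 genes (84.9%). Every duodenal, liver, celiac and iliac library in it held under 1000000 counts. The median log2 fold change of all genes was -2.35 for duodenal against ileal node and -2.15 for liver and celiac against non-digestive nodes. This count thus cannot separate library yield from the biology of the nodes. Among the 7 nodes with libraries of 1000000 counts or more, 11350 of 19702 genes (57.6%) differed, with Foxe1, Scg2 and Hoxc8 among the leading 8 (adjusted p = 2.42e-15, 3.75e-15 and 1.06e-13).

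**Figure D3:**
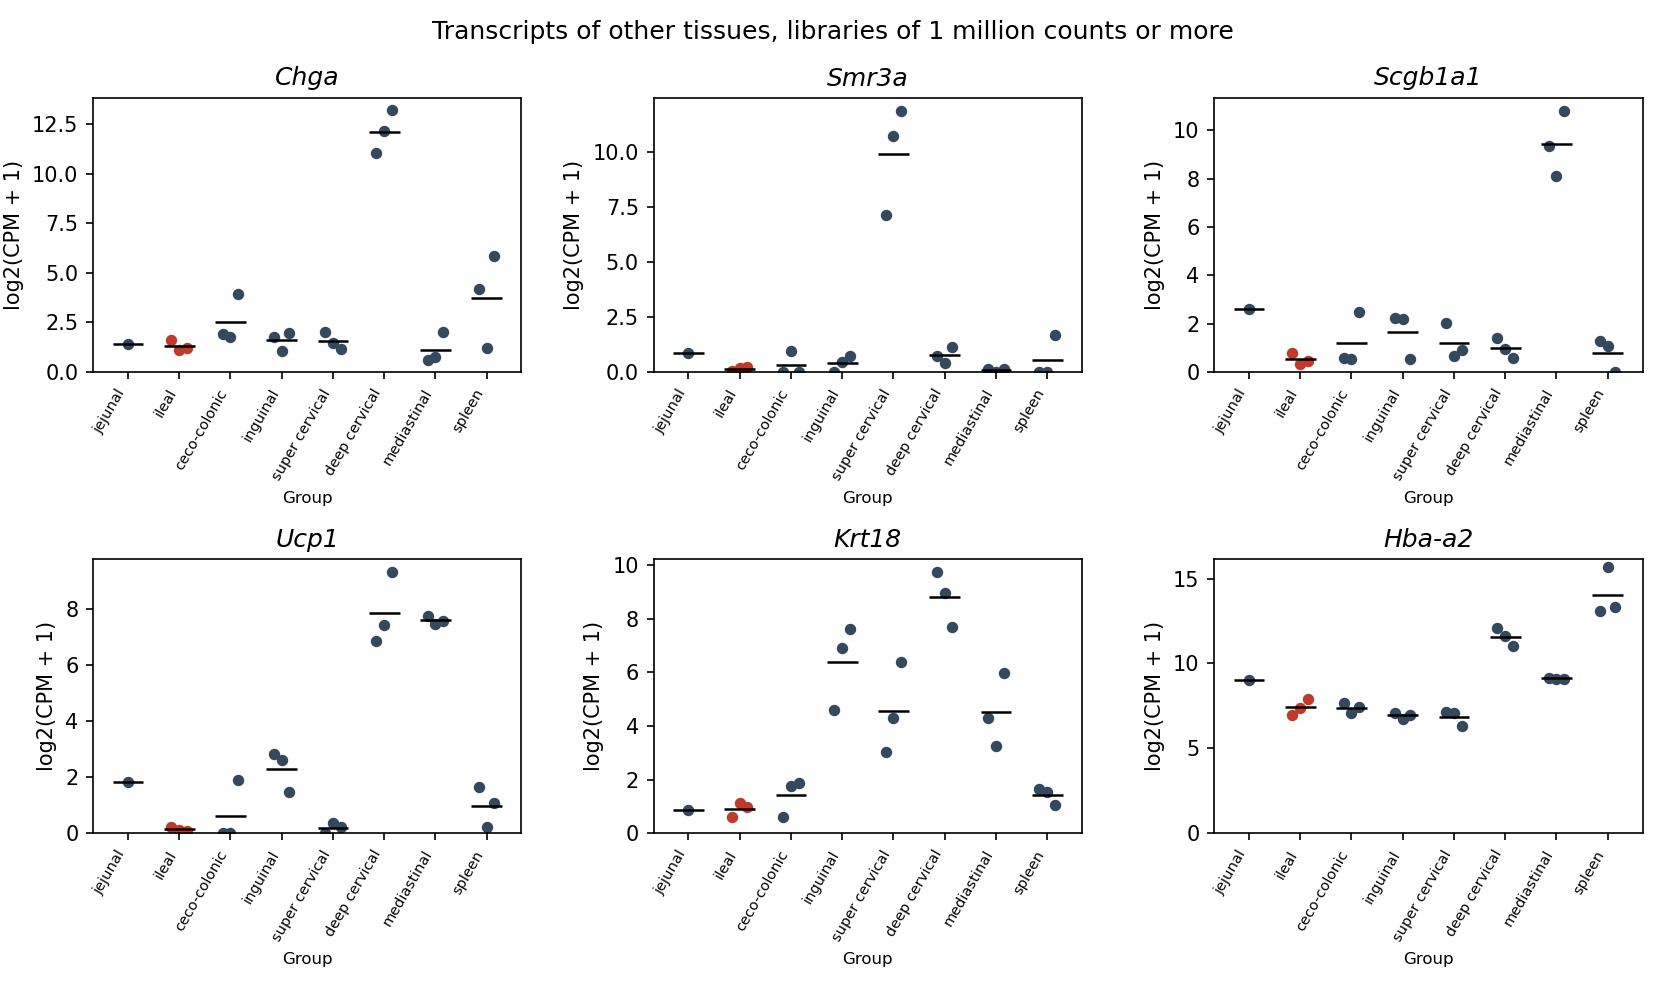
log2(CPM + 1) of Chga, Smr3a, Scgb1a1, Ucp1, Krt18 and Hba-a2 in libraries of 1000000 counts or more, 1 point per library, with ileal libraries in red and horizontal bars at group means. Chga averaged 5380 CPM in deep cervical, Smr3a 1820 CPM in super cervical and Scgb1a1 905 CPM in mediastinal node, and Hba-a2 averaged 23700 CPM in spleen.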

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

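The restriction to libraries of 1000000 counts or more, the contrasts within them with their alternatives, thinning and the removal of 3 features were chosen after the data were seen. The filter at 2 times the isotype control left 9929 genes to test in place of 16294. Thinning left 13289 in place of the 19702 of the deeper libraries. Counts under these 2 settings are thus out of fewer genes, and part of their fall follows from that alone. Testing only genes at 2 times the isotype control or more gave 1860 genes for small-intestinal against non-digestive nodes (4398 in the report), 1925 against the ceco-colonic node (3259), 4302 for duodenal against ileal (7445), 4448 for liver and celiac (7709), 2428 for nodes against spleen (4711) and 7589 among 11 nodes (13835). For small-intestinal against non-digestive nodes the count was 0 with node means as replicates in limma (747 at an unadjusted p under 0.05), 14 against all 8 other nodes, 813 in libraries of 1000000 counts or more (3 ileal and 1 jejunal against 4 nodes) and 733 after thinning those to 1000000, with 560 and 546 higher, where the report has 3537 of 4398 lower. Against the ceco-colonic node the values were 2135 with size factors, 17 in those deeper libraries and 11 after thinning. Nodes against spleen gave 2608 with size factors, 7085 with DESeq2 and 9815 in libraries of 1000000 or more. The F test gave 11350 in the deeper libraries, which hold 7 nodes, and 7068 after thinning those.

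In libraries of 1000000 counts or more, ileal against 4 non-digestive nodes (570) gave 913 with no filter, 1002 with limma voom, 877 with DESeq2 and 234 after thinning. Ileal against ceco-colonic node (52) gave 101 with size factors, 508 with no filter, 97 with the stricter filter, 92 with limma voom, 612 with DESeq2 and 33 after thinning. The F test among 7 nodes (11350) gave 6308 with limma voom and 7068 after thinning. With an estimated correlation the lists past the threshold fell from 3 to 0, 4 to 0, 11 to 0 and 11 to 3 in the planned contrasts with non-digestive, ceco-colonic, ileal and spleen as reference, and from 21 to 7, 7 to 0 and 12 to 0 in the ileal, ileal against ceco-colonic and spleen contrasts of the deeper libraries. At an unadjusted p under 0.05 the contrasts at 0 had 4, 2, 2, 1 and 4 lists in the order given.

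Leaving out each library in turn gave 3053 to 5432 genes for small-intestinal against non-digestive nodes, 1846 (without ceco-colonic replicate 3) to 4381 against the ceco-colonic node, 5403 to 7003 for duodenal against ileal, 6724 to 7774 for liver and celiac, 3346 to 4947 for nodes against spleen and 12992 to 13997 among 11 nodes. In the deeper libraries the ranges were 236 (without ileal replicate 2) to 670, 3 (without ceco-colonic replicate 3) to 66, 8438 to 11242 and 9152 to 12162. The isotype comparison's macrophage median moved between 0.95 and 1.19 and its adipocyte median between 0.97 and 2.35 with 1 jejunal library left out. Single jejunal libraries gave macrophage medians of 0 to 1.53. The report names other lists that moved.

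A replicate block gave 102 genes for ileal against ceco-colonic node and 6 lists, not 3, for small-intestinal against non-digestive nodes. Other counts of genes with the block were 4405, 3426, 7518, 7654, 4574, 13731, 599, 9685 and 11456, each within 1.5 times its value in the report. Libraries of one replicate number correlated by 0.0273 on average after group means were removed (-0.394 to 0.516 over 198 pairs), against -0.0134 for other numbers. Of 36 libraries 22 correlated best with their own number and 14 did not, so sharing is not excluded, though no label states it.

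Of values for single named genes under alternatives, 5645 kept their side of the threshold, 381 lost a call and 27 gained one, and 4 reversed. Csf1r in small-intestinal against non-digestive nodes (-1.30) was 0.27 in libraries of 1000000 or more and 0.49 after thinning, Cdyl in the same contrast ranged from -0.64 (without duodenal replicate 3) to 2.99 over left-out libraries, and Or4c10 in liver and celiac nodes from -0.16 (without liver replicate 3) to 5.83. Direction counts here only for genes past the threshold in their own contrast; for the others the estimate changed sign in 84 of 795 values, so no direction is given for them. This rule followed a first tally that counted those 84 as reversals. Depth limits the duodenal, liver, celiac, iliac and 2 of 3 jejunal libraries most, where 3 counts correspond to 3.27 to 13.5 CPM.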

Other observations

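The tests in this part were chosen after the result was seen, except the counts over other splits of the libraries for the ceco-colonic and duodenal contrasts, the F test and the 4 contrasts in libraries of 1000000 counts or more. Single transcripts known from glands, airway and fat, chosen after their values were seen, were high in particular nodes. Deep cervical node held 5380 ± 3710 CPM of Chga, a secretory granule protein of endocrine cells (SD, n = 3). Ucp1, the uncoupling protein of brown fat, averaged 306 ± 284 CPM there and 192 ± 19.2 in mediastinal node, against 0.102 ± 0.0563 in ileal node. The fixed adipocyte list did not pass for ileal against the 4 non-digestive nodes in libraries of 1000000 counts or more (camera adjusted p = 0.716). The growth factor Areg averaged 34.3 ± 22.9 CPM in inguinal node and 0.271 ± 0.117 in ileal node. Igha reached 1150 ± 222 CPM in ceco-colonic node, near the 1690 ± 288 of ileal node, and 6.23 ± 2.33 in inguinal node. Against the same 4 non-digestive nodes the ceco-colonic node had 809 genes past the threshold, 554 higher and 255 lower, with Nkx2-3 up by 6.88 ± 0.77 and Hoxc10 by 6.33 ± 0.68 (adjusted p = 0.000149 and 1.42e-05).

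Sex-linked genes differed between libraries with the same replicate number. Among libraries numbered 1, the Y-linked gene Ddx3y stood at 62.7 CPM in ceco-colonic and 65.5 in deep cervical node, and at 2.13 in ileal and 0.773 in mediastinal node. It also differed within a node, at 51.6 CPM in ileal replicate 3 against 1.88 in ileal replicate 2. Ileal replicate 3 held 101 CPM of the sex-linked gene Xist as well. Sex entered no model. Correlation with the isotype library across genes was 0.788 to 0.857 for spleen, 0.809 for inguinal replicate 1, 0.798 for iliac replicate 3 and 0.317 to 0.406 for mediastinal node; genes are not independent replicates.

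The excess of genes lower in small-intestinal nodes (3537 of 4398) cannot be told apart from a difference in library yield. Among libraries of 1000000 counts or more 31.1% of calls were lower, but that restriction also removes the duodenal and iliac nodes and most jejunal libraries, so it does not isolate yield. Leaving out the 3 ribosomal features left 80.2% of calls lower, but it moved no log2 fold change by more than 0.07, so whether these features are the cause stays open. A difference particular to small-intestinal drainage stays open too: 9 of the 56 splits of the 8 nodes into 3 and 5 gave as many lower genes, up to 7684 for duodenal, jejunal and iliac nodes, yet all 9 had the duodenal node among the 3, and the 10 splits with no small-intestinal node there gave at most 2671. The duodenal libraries were all shallow, so yield and biology of that node are confounded.

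Thyroid and parathyroid transcripts outside the deep cervical node may be reads carried over between libraries. Summed over the 33 other libraries, counts of Tg, Pth, Calca and Chga kept their proportions, with 4120, 2500, 3110 and 3680 outside counts per 1000000 deep cervical counts, a ratio of highest to lowest of 1.65. The ileal libraries alone held 86, 17, 29 and 127 counts of these genes. The deep cervical libraries held 239861, 120217, 198030 and 246866, so a single site can depart from the pooled proportions. Gland tissue could keep such proportions too, so this ratio does not single out carried-over reads. The 3 spleen libraries held 63 Tg counts, and as the spleen adjoins no thyroid, collected gland tissue was argued against as their source. Spleen counts cannot show whether gland tissue came with other nodes, so that stays open. No biological explanation was tested, and free RNA shared during handling would look alike and was not tested.

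Lymphatic endothelium genes, of which 4 of 14 listed are also in another list (Itga2b, Madcam1, Marco and Pdpn), were higher in the ileal node, and after thinning to 1000000 counts 5 members stayed higher of 9 still measured, between the bounds of 2 and 6 written for that test. The calls of Prox1, Flt4 and Stab2 ended at 1.49, 2.03 and 2.06 (1.67, 1.69 and 2.29 before) as their standard errors rose from 0.36, 0.38 and 0.50 to 0.49, 0.57 and 0.59. The folds, examined because that count was undecided, had a median of 1.69 before (SD 0.63) and 2.03 after (SD 0.48) with 9 of 9 positive. Random thinning leaves the expected share of a gene in its library unchanged, so these folds were bound to stay similar and cannot decide on depth. The rule for reading them was also written after their values were seen. Depth as a cause stays open for all 13 members. Against the more deeply sequenced mediastinal node 10 of 13 were positive, 3 past the threshold, and yield before sequencing and the biology of the node were not tested. A larger share of all stromal cells was argued against by the folds, since fibroblastic reticular genes had a median log2 fold change of 0.06 against 1.67. A permutation of genes between these lists gave p = 1e-05, two-sided, the smallest that 1e+05 resamples can give. Genes in the same libraries are not independent replicates, so that p does not measure the spread between libraries. A rise shared with the ceco-colonic node was argued against too, with 1 member higher in that node and a median of 0.26. Whether other small-intestinal nodes share the rise was not tested. The only jejunal library of this depth held 6816 CPM of Marco and 26.9 CPM of Lyve1. Ileal libraries held at least 5740 and 54.5 CPM of these genes.

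Other splits of the same libraries were counted for each number of genes. For small-intestinal against non-digestive nodes 1 of 60 splits, the real one, gave as many as 4398 genes and the highest other gave 1483. The real split alone also reached its count for the ceco-colonic contrast (1 of 60, highest other 2017), liver and celiac (1 of 60, 2401), spleen (1 of 60, 1735) and the F test (1 of 60, 1434). In libraries of 1000000 counts or more it did so for the spleen contrast (1 of 60, 6700) and the F test (1 of 60, 1842). These splits break up the 3 libraries of a node, so a group mixes sites, which can widen its spread and lower its count. They speak only to a random assignment of single libraries, not to whether the chosen sites differ more than others would. With nodes kept whole 21 of 56 splits gave as many as 4398, so a chance assignment of nodes could not be excluded there. The other contrasts were not split by node, and a chance assignment of nodes was not tested for them. For ileal against the 4 other nodes chance could not be excluded, since 7 of 60 splits gave 570 genes or more and the highest, with mediastinal replicates 2 and 3 and deep cervical replicate 3 on one side, gave 5709, which points to a structure among the reference nodes. For duodenal against ileal node (7445, highest other 38) and ileal against ceco-colonic node (52, highest other 0) the 10 splits are too few for a share under 0.05.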
